A study of Mus musculus with 9 samples.

How the data were processed

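RNA was measured in 9 parietal mitral valve leaflets of mice at postnatal day 5, each leaflet 1 sample, in 5 controls (floxed Sox9) and 4 mice that also carried Wt1-Cre. Per the labels' protocols, total RNA was extracted from each microdissected leaflet with a micro-scale column kit, samples of low RNA integrity were excluded, and libraries were made by a commercial provider with a protocol for low input. Per the submitters' processing notes, the mm10 build, STAR 2.7.8a, Partek and DESeq2 were used. The read counter, the annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Values of ribosomal protein genes, which have many processed pseudogenes, of paralogs such as the actin genes, and of overlapping or antisense genes are uncertain to that extent.

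The authors deposited, for 13856 genes, a signal per library, which is a read count estimate divided by a library size factor. That reading comes from the values: 83.7 to 85.4% of low values (under 60) were whole multiples of a library's step within a tolerance of 0.03 and the others were fractional. Because so many were not whole, no count test was run, although a count test had been planned for the case that the files held counts, and limma on log values, the test fixed for normalised values, took its place. The authors' deposited comparison gives a step-up false discovery rate (an adjusted p-value), a log2 ratio and a signed fold change per gene. The 3 comparison columns occur in both deposited tables, with 0 values that differ. The log2 ratio differed from the log2 ratio of the group means of the deposited signal by a median of 0.0014.

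The columns of the deposited values show the group of each library by a prefix, with a number that occurs in no label, so libraries are named here by group and column number and no control is paired with a littermate. The column totals were 14960000 to 17030000. Dividing them by the step gave about 11500000 to 20900000 reads per library. Since the low values were only partly whole, that depth is approximate and no counting intervals are given.

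Values were analysed as log2(value + 1), and fold changes are on that scale, which understates the change of low genes. Genes with a value of at least 10 in at least 4 libraries were tested, 13599 genes, and 257 were left out. limma 3.58.1 in R 4.3.3 was fitted to all 9 libraries with the group as the only term and a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Exact two-sided permutation tests of single genes used all 126 regroupings of 5 against 4, and their smallest possible p is 0.00794. Gene lists were tested with limma's camera at an inter-gene correlation of 0.01, with adjustment over the 34 of 35 lists that had at least 5 measured members. None of the 12 lists called by camera was called with an estimated correlation. Lists covered valve matrix, signalling, metabolism, inflammation and the cell types a dissected leaflet could hold, and they share some members. They were fixed before the data were examined, as were the main test and most of the other settings tried. After the data were examined 4 short lists were added: dendritic cell markers, MHC class II genes, macrophage genes outside antigen presentation, and X-linked genes that escape inactivation. Gene coordinates, GC content and length came from GENCODE M21, on the same build as the submitters' notes name, and 99.2% of the genes were matched with Python 3.11.15.

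The named genes follow a rule fixed beforehand: Sox9, Wt1 and Cd109 always (Wt1 was not analysed here), then the 12 largest changes in each direction among genes past the threshold with at least median abundance, filled from called genes of any abundance. As no gene passed here, the 6 smallest p-values in each direction are named instead, and the first form of the rule was applied to the authors' deposited table. Predicted genes, pseudogenes and mitochondrial-genome genes are counted but not named. Up to 4 members with the smallest p are named per list. Kdr, Col1a1, Col2a1 and the further members that passed within a list were chosen after their values were seen.

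On simulated data with the spread of the 9 libraries and 200 of 13599 genes changed, over 5 runs, limma recovered 18.5% of genes changed 1.5-fold, 57.6% of those changed 2-fold and 86.4% of those changed 4-fold, with 5.2% false calls. In 20 of 20 simulated runs camera detected a list of 25 genes raised 1.3-fold, at an unadjusted p under 0.05. The simulated genes were drawn independently, while members of real lists move together, with an estimated correlation of 0.74 for ribosomal proteins. That simulation therefore does not show how often camera calls a real list falsely. Alternatives covered scaling, filter, pseudocount, threshold, set test, each library left out, variance moderation, library weights, a GC and length adjustment, a hidden component and the series given by the first digit of the column number.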

Results

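Sox9 is a transcription factor of cartilage and valve matrix programmes, and the comparison asked how its deletion in the epicardial lineage changes the parietal leaflet of the mitral valve, a leaflet that epicardium-derived cells populate. RNA was sequenced from single leaflets of mice at postnatal day 5. There were 5 libraries from controls with floxed Sox9 alleles and 4 from littermates that also carried Wt1-Cre, a recombinase driven in the epicardium. The labels call the samples biological replicates. The deposited values were normalised read counts for 13856 genes, and their totals ran from 14960000 to 17030000 per library. The value of 1 read, read off the spacing of low values, put the depth at about 11500000 to 20900000 reads per library, lowest in library 407 of the labelled knockouts and highest in library 305 of the same group.

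Sox9 RNA was not lower in the libraries labelled knockout. Its normalised read count was 3877 ± 1284 (SD, n = 5) in controls and 4462 ± 1073 (SD, n = 4) in the labelled knockouts, a log2 fold change of 0.23 (SE 0.24, 95% interval -0.30 to 0.76). The difference was smaller than the spread between leaflets (exact two-sided permutation p = 0.468, limma adjusted p = 0.783). Control libraries ranged from 2381 to 5904 and labelled knockout libraries from 3007 to 5500. Sox9 lies on chromosome 11 from 112782224 to 112787760 in the mm10 build, and the value covers the gene as a whole, so reads from the floxed part were not measured separately. The target gene therefore does not check the genotype labels, and every direction below rests on the labels alone. Wt1, the Cre driver gene, was not analysed here. Cd109, which encodes a co-receptor that restrains TGF-beta signalling, read 1396 ± 364 (SD, n = 5) in controls and 1952 ± 342 (SD, n = 4) in the labelled knockouts, a log2 fold change of 0.51 (SE 0.19). Its exact permutation p was 0.0476 and its limma adjusted p 0.535.

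The smallest p-values in the genome-wide comparison belonged to Abca8a, a lipid transporter, and Clu, a secreted chaperone. Abca8a averaged 625.5 ± 67.9 (SD, n = 5) in controls and 276.6 ± 48.9 (SD, n = 4) in libraries labelled knockout, a log2 fold change of -1.19 (SE 0.15). Clu averaged 7104 ± 852 (SD, n = 5) and 12280 ± 835 (SD, n = 4), a log2 fold change of 0.80 (SE 0.10). For both, the groups did not overlap, and the limma adjusted p was 0.0667. Among the other genes with higher means in the labelled knockouts were 3 that encode chains of the MHC class II antigen-presenting molecules and lie together on chromosome 17. H2-Eb1 had a log2 fold change of 1.27 (SE 0.20), H2-Aa 1.22 (SE 0.19) and H2-Ab1 1.10 (SE 0.18), each with a limma adjusted p of 0.135. Masp1, a serine protease of the lectin complement pathway, stood at 118.2 ± 23.4 (SD, n = 5) against 286.8 ± 58.4 (SD, n = 4), and S100a4, a calcium-binding protein, at 149.4 ± 46.5 against 356.8 ± 91.7.

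Lower means in the labelled knockouts were found for Csgalnact1, which starts chondroitin sulfate chains, at 549.2 ± 71.4 (SD, n = 5) against 308.6 ± 26.5 (SD, n = 4), and for Corin, the protease that activates atrial natriuretic peptide, at 302.9 ± 62.5 against 114.4 ± 35.3. Angpt2, a ligand of the endothelial receptor Tek, read 201.7 ± 65.7 against 52.9 ± 35.7, a log2 fold change of -2.05 (SE 0.38). Mme, the peptidase neprilysin, read 292.9 ± 101.2 against 89.4 ± 44.3, and Hjurp, a centromere histone chaperone, 527.7 ± 63.4 against 321.3 ± 36.1. The limma adjusted p of these genes lay between 0.135 and 0.332. No gene passed an adjusted p of 0.05: limma called 0 of the 13599 genes tested. At an unadjusted p under 0.05 there were 1188 genes, 592 higher and 596 lower, where 680 would be found by chance. That count was 651 without labelled knockout library 402, 735 without control library 404 and 2131 without labelled knockout library 305. In all, 12 of 100 groupings of the libraries, the real one included, reached it, with up to 3238 genes in another grouping. The groups did not overlap in 393 genes, 2.89% of those tested, where chance gives 1.59%.

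**Figure D1:**
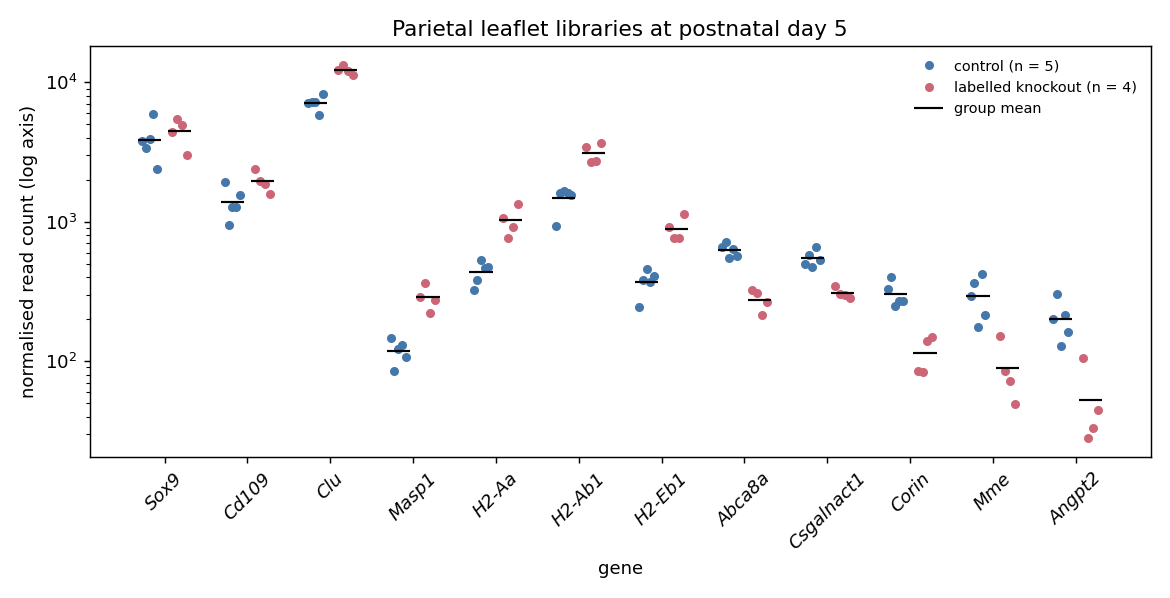
Normalised read count (log axis) of 12 genes in each library, with 5 control and 4 labelled knockout libraries as points and the group mean as a bar. Sox9 overlaps between the groups, with controls from 2381 to 5904 and labelled knockouts from 3007 to 5500, while the Clu values of the labelled knockouts, from 11310 to 13340, lie above the highest control at 8232.

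The authors' deposited table called more genes from the same libraries. In the authors' deposited table a false discovery rate under 0.05 was given to 23 genes, with 7 higher and 16 lower in the labelled knockouts, and 14 of the 23 had an absolute log2 ratio of at least 1. The lower genes in the authors' deposited table included Abca8a (FDR 8.6e-05, log2 ratio -1.18), Corin (FDR 8.6e-05, -1.41), Mme (FDR 0.000579, -1.70), Csgalnact1 (FDR 0.00805) and Angpt2 (FDR 0.0265). Ogn, a small leucine-rich proteoglycan, had a log2 ratio of -0.975 in the authors' deposited table, the calcium pump gene Atp2a3 -0.81, Rasgef1b -0.562 and Olfml1 -0.433. The authors' deposited table also listed Ttyh1 at -2.03, Enpp6 at -1.15 and the long non-coding RNA Flicr at -2.46, whose lowest labelled knockout value was 1.04, about the value of 1 read. The higher genes in the authors' deposited table were Clu (FDR 0.00982), Masp1, S100a4, Igsf9b and Cd72 (each FDR 0.0173), Evi2b (FDR 0.0327) and the collagen receptor kinase Ddr1 (FDR 0.0399). In the limma fit made here all 23 of these genes had the same direction and groups that did not overlap, with adjusted p from 0.0667 to 0.451. Both comparisons used the same 9 libraries, so the shared direction and the separation are no independent support.

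Complement and antigen presentation genes and macrophage markers stood higher as groups in the libraries labelled knockout. The list of complement and antigen presentation genes rose by a mean log2 of 0.31, with SDs of the library means of 0.03 (n = 5) and 0.19 (n = 4), and 19 of its 25 measured members were higher. All 4 labelled knockout libraries lay above all controls, the limma camera adjusted p was 6.5e-06, and the adjusted p was 0.295 with an estimated correlation. Adjusted over the list alone, 8 members passed, C1qa, C1qb, C1qc, H2-Aa, H2-Ab1, H2-Eb1, Cd74 and H2-DMa, against 0 over all genes tested. Cd74, the invariant chain of MHC class II, averaged 1148 ± 412 (SD, n = 5) and 3038 ± 1026 (SD, n = 4). The list of macrophage markers also rose, by a mean log2 of 0.33 with 22 of 25 members higher (limma camera adjusted p = 2.41e-08, adjusted p = 0.498 with an estimated correlation). The Fc receptor gamma chain gene Fcer1g read 559.6 ± 111.4 against 883.6 ± 104.5, the complement gene C1qc 1222 ± 174 against 1727 ± 92, and 6 macrophage markers passed adjusted over the list alone, against 0 over all genes. The C1q genes belong to both lists. Cd79b, a B-cell receptor component, stood at 8.66 ± 3.92 (SD, n = 5) against 27.3 ± 9.8 (SD, n = 4), with groups that did not overlap.

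Contractile and mineralisation genes were also higher as groups. The list of smooth muscle and myofibroblast markers rose by a mean log2 of 0.44 (SDs 0.26, n = 5, and 0.13, n = 4), with 14 of 19 members higher and a limma camera adjusted p of 0.00136, and the adjusted p was 0.568 with an estimated correlation. Acta2, smooth muscle actin, averaged 7288 ± 2085 (SD, n = 5) and 12030 ± 1817 (SD, n = 4), Tpm2, a tropomyosin, 1191 ± 128 and 1746 ± 191, and Actg2 105.5 ± 63.4 and 375.9 ± 249.6. These 3 passed adjusted over the list alone, against 0 over all genes. Osteogenic and mineralisation genes rose by a mean log2 of 0.40 (SDs 0.39, n = 5, and 0.22, n = 4), with 11 of 13 members higher (limma camera adjusted p = 0.00326, adjusted p = 0.568 with an estimated correlation). Only 1 labelled knockout library lay above all controls, and the library means gave an exact permutation p of 0.111. Spp1, which encodes osteopontin, had a log2 fold change of 0.78 (SE 0.24), Msx2 1.18 (SE 0.39) and Runx2, the osteoblast transcription factor, 1.00 (SE 0.47), and 0 members passed adjusted over the list alone. Values of the last 2 genes were low: Msx2 averaged 15.18 in controls and 37.65 in the labelled knockouts, and Runx2 23.69 and 44.38. Without labelled knockout library 305 the osteogenic list had an adjusted p of 0.0708, and with members of several lists removed 0.103. At a minimum value of 50 its mean was 0.255.

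Proteoglycan and cartilage genes were lower as groups. The list of proteoglycans and hyaluronan genes fell by 0.40 on the mean log2 scale (SDs 0.26, n = 5, and 0.31, n = 4), with 18 of 23 members lower (limma camera adjusted p = 0.00116, adjusted p = 0.584 with an estimated correlation). Ogn averaged 1799 ± 276 (SD, n = 5) and 916 ± 333 (SD, n = 4), Ecm2 1860 ± 290 and 1252 ± 225, Hapln1, which links hyaluronan to proteoglycans, 1210 ± 99 and 898 ± 134, and Epyc 31.8 ± 11.9 and 8.90 ± 5.68. These 4 passed adjusted over the list alone, against 0 over all genes. Cartilage and chondrogenic genes, the programme Sox9 is best known for, fell by 0.35 (limma camera adjusted p = 0.0192, adjusted p = 0.956 with an estimated correlation), with 14 of 22 members lower. The cartilage collagen genes Col9a2, at 597 ± 204 against 289 ± 88, and Col9a3, at 4332 ± 726 against 2996 ± 531, passed adjusted over the list alone together with Hapln1 and Epyc, while Col2a1 had a log2 fold change of -0.84 (SE 0.68) and did not. Without control library 201 the adjusted p was 0.218 for proteoglycans and 0.207 for cartilage genes, whose mean was then -0.201. With the column-number series as a block, chosen after the data were seen, it was 0.278 and 0.185, and within the series starting with 4 it was 0.328 and 0.0885. The proteoglycan mean was -0.259 without labelled knockout library 402 and -0.242 at a minimum value of 50. The cartilage call also ended without control library 404 (0.0573), without labelled knockout library 402 (mean -0.162, adjusted p = 0.224), at a minimum value of 50 (0.0619), with the GC and length trends removed (0.0573) and with members of several lists removed (0.165). The proteoglycan call also ended without both control library 201 and labelled knockout library 305 (0.0883).

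Endothelial and endocardial markers fell by 0.26 on the mean log2 scale (SDs 0.22, n = 5, and 0.28, n = 4), with 21 of 26 members lower (limma camera adjusted p = 9.47e-05, adjusted p = 0.584 with an estimated correlation). Prox1, a transcription factor of lymphatic and valve endothelium, averaged 1044 ± 274 (SD, n = 5) and 616 ± 122 (SD, n = 4), the angiopoietin receptor Tek 3716 ± 271 and 2662 ± 661, Tie1 4803 ± 505 and 3740 ± 567, and the VEGF receptor Kdr 1525 ± 310 and 1031 ± 328. Adjusted over the list alone 0 members passed, and the list mean was -0.146 without labelled knockout library 402. Only 1 labelled knockout library lay below all controls, and the library means of the endothelial list gave an exact permutation p of 0.167. Notch signalling genes fell by 0.11, with 15 of 19 members lower (limma camera adjusted p = 0.0192, adjusted p = 0.568 with an estimated correlation). The ligand gene Dll1 had a log2 fold change of -0.63 (SE 0.22) and Jag1 -0.35 (SE 0.15), while Lfng was higher, at 0.84 (SE 0.33). Labelled knockout library 407 lay above every control, and the library means gave an exact permutation p of 0.516. The Notch call ended without control library 403 (mean -0.059, adjusted p = 0.0842), without labelled knockout library 305 (mean -0.016, adjusted p = 0.196), within the column-number series starting with 4 (0.0633), with the first residual component as a covariate (0.0512), without both control library 201 and labelled knockout library 305 (mean -0.056, adjusted p = 0.164) and with members of several lists removed (0.147). Its mean was -0.173 with library weights, -0.071 without control library 404, -0.07 without labelled knockout library 401 and -0.249 without 407.

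Ribosomal and energy metabolism genes were slightly higher. All 28 measured cytosolic ribosomal protein genes had higher means in the labelled knockouts, by a mean log2 of 0.26 (limma camera adjusted p = 5.21e-13, adjusted p = 0.568 with an estimated correlation), for example Rpl18 at 3978 ± 394 (SD, n = 5) against 5121 ± 533 (SD, n = 4). Across genes, which are not independent replicates, the log2 fold change correlated with GC content (Spearman rho 0.28) and with transcript length (rho -0.32), and after both trends were removed the ribosomal mean was 0.10 (95% interval -0.07 to 0.28). Oxidative phosphorylation genes rose by 0.10 with 23 of 27 members higher (limma camera adjusted p = 0.00116, adjusted p = 0.956 with an estimated correlation), and hypoxia and glycolysis genes by 0.14 with 14 of 23 higher (limma camera adjusted p = 0.0192, adjusted p = 0.584 with an estimated correlation). Eno1, a glycolytic enzyme, read 7342 ± 254 against 8925 ± 449. The oxidative phosphorylation mean was -0.008 after the GC and length trends were removed, and its call ended without control library 201 (mean 0.023, adjusted p = 0.0569) and with the column-number series as a block (0.0683), while its mean was 0.183 without labelled knockout library 305 and 0.045 without 401. The glycolysis call ended without control library 403 (0.0722) or 404 (mean 0.089, adjusted p = 0.0922), without labelled knockout library 305 (0.196), without both it and control library 201 (0.164), with quantile normalization (0.057), within the series starting with 4 (0.101) and with both trends removed (0.222).

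Cardiomyocyte markers, a measure of attached heart muscle in the dissected leaflet, rose by a mean log2 of 0.42 (limma camera adjusted p = 0.0347, adjusted p = 0.956 with an estimated correlation), yet the library means spanned 3.36 on the log2 scale. The mean was -0.023 without control library 201 and in the series block, which leaves it out, and the call also ended without control library 404 (adjusted p = 0.149), without labelled knockout library 401 (mean 0.035, adjusted p = 0.895) or 407 (0.0708), within the column-number series starting with 4 (mean 0.166, adjusted p = 0.561) and without both control library 201 and labelled knockout library 305 (mean 0.137, adjusted p = 0.73). It ended as well with library weights (0.0831), with the first residual component as a covariate (0.0583), with the GC and length trends removed (0.068), at a minimum value of 50 (0.0528) and with members of several lists removed (0.055). The list mean was 0.681 without control library 406 and 0.709 without labelled knockout library 402. Atrial markers averaged 0.285 (limma camera adjusted p = 0.699) and ventricular markers 0.23 (0.695). Without labelled knockout library 401 these means were 0.047 and -0.057. Without control library 201 they were 0.152 and -0.114, without labelled knockout library 402 they were 0.44 and 0.463, and without labelled knockout library 407 the ventricular mean was -0.031.

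**Figure D2:**
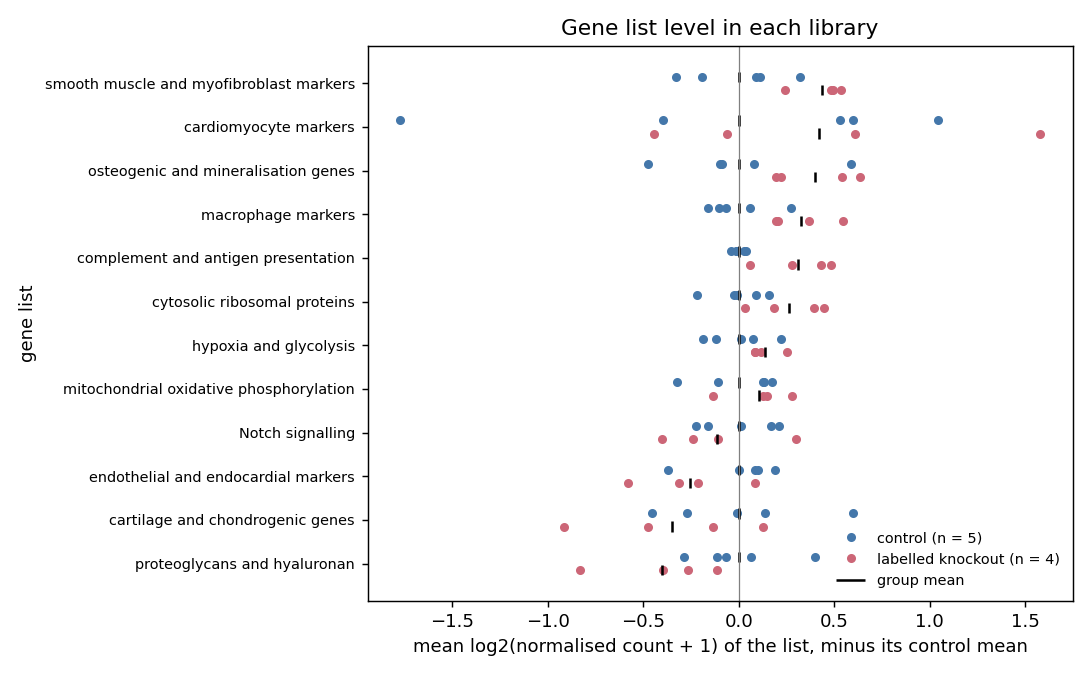
Mean log2(normalised count + 1) of the 12 gene lists called by camera in each library, relative to the control mean of the list, with 5 control and 4 labelled knockout libraries as points and group means as bars. All 4 labelled knockout libraries lie above the controls for complement and antigen presentation, while the cardiomyocyte list spans 3.36 log2 units.

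The main structural matrix of the leaflet showed no called difference. Fibrillar and network collagens averaged a log2 fold change of 0.01 with a median of -0.057 (limma camera adjusted p = 0.99), and Col1a1, the most familiar member, had a log2 fold change of -0.04 (SE 0.30). The members of smallest p went both ways, with Col5a3 at 0.68 (SE 0.19) and Col15a1 at 0.59 (SE 0.20), but Col6a6 at -1.15 (SE 0.38) and Col18a1 at -0.27 (SE 0.11). Adjusted over the list alone 0 of them passed. Collagen processing enzymes averaged 0.07 (0.695), elastic fibre genes 0.03 with a median of -0.009 (0.763) and matrix proteases and inhibitors 0.02 with a median of -0.014 (0.99), where the cathepsin gene Ctss, also a macrophage marker, passed adjusted over the list alone, against 0 over all genes. Matricellular proteins averaged -0.05 (0.75), but 4 members passed adjusted over the list alone, against 0 over all genes: Sparcl1, at 2135 ± 452 (SD, n = 5) against 1304 ± 126 (SD, n = 4), Matn2, with a log2 fold change of -0.71 (SE 0.18), Ccn4 at 0.65 (SE 0.20) and Spp1. Valve interstitial and fibroblast markers averaged -0.01 (0.848), with the mesenchymal receptor gene Pdgfra at 5099 ± 1042 against 3236 ± 704.

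Among signalling lists, valve and cushion transcription factors averaged 0.09 (limma camera adjusted p = 0.911) and TGF-beta and BMP signalling -0.085 (0.353). Wnt signalling averaged 0.11 (0.699), with members on either side, as Wnt11 had a log2 fold change of 0.96 (SE 0.31) and Wnt5a -0.39 (SE 0.11). The Wnt mean was 0.055 without control library 201, 0.058 without labelled knockout library 407 and 0.179 without labelled knockout library 305. Retinoic acid genes averaged 0.05 with a median of -0.017 (0.823), cell cycle genes -0.03 (0.699), interferon response genes 0.305 (0.135), cytokines and acute inflammation 0.27 (0.478) and immediate-early and heat shock genes -0.08 (0.99). The interferon mean was 0.118 without labelled knockout library 407, and the cytokine mean was -0.141 without labelled knockout library 305 and 0.019 without control library 304. Of the 22 tested lists that were not called, 15 turned sign in their mean without 1 of the libraries, and the other 7 moved by over 1.5 times.

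Of the remaining cell types, epicardial and mesothelial markers averaged -0.18 (limma camera adjusted p = 0.996), but their members moved apart. Their mean was -0.046 without control library 406, -0.061 without labelled knockout library 402, -0.112 without control library 403 and -0.319 without control library 201. Clu and Lrrn4, a mesothelial surface protein at 21.9 ± 11.5 (SD, n = 5) against 4.38 ± 1.33 (SD, n = 4), passed adjusted over the list alone, against 0 over all genes. In limma's fry test for change in either direction, which does not set a list against other genes, 4 lists passed after adjustment: epicardial markers (1.92e-08), complement and antigen presentation (0.000552), macrophage markers (0.00544) and retinoic acid genes (0.00685). The epicardial list holds Clu, which had 1 of the smallest p-values of all genes tested, so its value may largely restate that gene. Melanocyte markers averaged -0.73 (limma camera adjusted p = 0.135), neutrophil and mast cell markers 0.21 (0.695), Schwann and neuronal markers 0.04 (0.763), and adipocyte markers -0.13 (0.99). The melanocyte mean was 0.341 without labelled knockout library 401, and the neutrophil mean was -0.306 without labelled knockout library 305 and -0.10 without control library 304. The neuronal tubulin gene Tubb3, at 598.6 ± 119.3 (SD, n = 5) against 906.6 ± 55.7 (SD, n = 4), passed adjusted over the Schwann and neuronal list alone, against 0 over all genes. Erythroid and platelet markers averaged -0.22 (limma camera adjusted p = 0.99), where camera's direction was higher. Their mean was 0.247 without labelled knockout library 305. The 3 measured lymphocyte markers, too few for the list test, averaged 0.69, and of these Cd79b passed adjusted over the list alone, against 0 over all genes.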

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

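The tests of MHC class II against other macrophage genes, of the ribosomal list by permutation, and both Sox9 tests were chosen after the results were seen, and the GC and length test of the MHC class II genes was added after the first results, before its own value was seen. The use of 95% intervals to judge the GC and length tests of the other lists was also chosen afterwards. Of 120 groups of libraries examined, 8 held a library far from the rest, where chance gives about 6. H2-Ab1 was 938.6 in control library 201 and 1551 to 1663 in the other controls. S100a4 was 231 in control library 403 and 122.4 to 144.3 in the others. Cd72 was 273.6 in labelled knockout library 407 and 196.3 to 201 in the others, and Ogn was 421.4 in labelled knockout library 402 and 1023 to 1146 in the others. Among list means relative to the controls, the elastic fibre list stood at 0.393 in control library 201, the interferon list at 0.284 in control library 403, and the melanocyte list at -2.114 in control library 403 and -3.952 in labelled knockout library 401.

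The MHC class II genes averaged a log2 fold change of 1.07 (95% interval 0.67 to 1.47), with all 4 labelled knockout libraries above the controls for H2-Aa, H2-Ab1, H2-Eb1 and Cd74. A larger share of macrophages with all their genes raised alike is argued against as the whole source. The MHC class II genes exceeded 20 other macrophage genes, which averaged 0.33, by 0.744 (95% interval 0.21 to 1.28). The excess was 0.615 (0.16 to 1.07) without the 3 of smallest p and 0.738 (0.11 to 1.37) over the whole class by gene name. The class was picked after its values were seen, so no p is given. The 20 genes did not move alike, with Fcer1g at 0.674 and Lyz2 at 0.605 but Mrc1 at -0.205 and Csf1r at 0.062. More macrophages of a kind rich in MHC class II were not tested and stay open. A GC and length trend as the whole cause is argued against too, as the mean after adjustment was 0.983 with a lower 95% bound of 0.618, above 50% of the unadjusted mean. For the wider complement and antigen presentation list the adjusted mean was 0.243, above 50% of the unadjusted 0.312 as the bound set beforehand asked, and camera still called it (adjusted p = 0.000268), but the 95% interval of 0 to 0.487 spans that bound (exact permutation p = 0.0635), so the trend stays open there. The macrophage list stood at 0.327 before adjustment and 0.263 after (-0.075 to 0.6, exact permutation p = 0.135). Camera still called it (adjusted p = 1.22e-05), but its interval also spans 50% of the unadjusted mean, so the trend stays open for it too. More dendritic cells may contribute: their 7 measured markers averaged 0.356 with an upper bound of 0.824, below the MHC mean as the bound set beforehand asked, but that bound was set wrongly, since it ignored the interval of the MHC mean, which starts at 0.67, and markers such as Cst3, at 9231 to 12635 in the 9 libraries, would hide a small share. B cells, which also carry MHC class II, stay open too, as Cd79b was higher in all 4 labelled knockout libraries than in any control while only 3 lymphocyte markers were measured. An effect of genotype also remains open, and the pattern is a hypothesis.

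The ribosomal protein list was higher by 0.26, with a camera adjusted p of 5.21e-13. A GC and length trend between libraries could account for part or all of it and cannot be told apart from other causes: the mean after adjustment was 0.102, under 50% of the unadjusted mean, but its 95% interval of -0.07 to 0.28 spans that bound (exact permutation p = 0.198), and camera still called the list (adjusted p = 0.000354). The spread of the whole list between libraries is open as well, because the library means gave an exact permutation p of 0.0556. No biological cause was tested beyond the genotype labels.

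Sox9 RNA was not lower in the libraries labelled knockout. A loss of 50% or more of the measured RNA is argued against by the lower 95% bound of the log2 fold change, -0.302, which allows a fall of at most 18.9%. A loss in a minority of the Sox9-expressing cells may still be present and cannot be told apart from none, since the chondrogenic list gave an exact permutation p of 0.254. Transcripts that lose floxed exons but are still counted, and a wrong label, were not tested.

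With 0 genes called for the real groups, the count of splits that reach it, 100 of the 100 drawn from 126, was fixed in advance and says nothing about chance. The highest other split gave 193 genes and put control libraries 201 and 304 with labelled knockout libraries 305 and 401. Libraries 201, 304 and 305 are all those outside the column numbers 401 to 407, and they alone scored positive on the first principal component. Library 401 scored -9.3 there, so the split did not follow the column-number series fully. With 401 exchanged for library 403, 404, 402 or 407 the split called 0 genes, and with 406 it called 1. The 193 genes therefore depended on library 401 as well. Chance cannot be excluded for the other counts. For genes at unadjusted p under 0.05, 12 of 100 splits reached the real 1188, and the highest other gave 3238. For lists called by camera, 38 of 100 splits reached the real 12, and the highest other gave 17.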

How the results depend on the processing

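Robust variance moderation, library weights, the GC and length adjustment, the residual component, the column-number series, the exact test of list means and leaving out both control 201 and labelled knockout 305, which share the high end of the first principal component, were chosen after seeing the data. The count of 0 called genes became 2 with robust moderation (Abca8a and Clu), 6 with the residual component as a covariate (also H2-Aa, H2-Ab1, H2-Eb1 and Sparcl1) and 2 at an adjusted p under 0.10, and was 0 in the other settings and without any single library. The residual component was computed from the residuals of these same values after the group was fitted. It leaves the fold changes unchanged and takes out residual spread by construction, so its added calls are no independent support. The cause of the calls with robust moderation was not tested. The 12 called lists became 0 with the directional form of fry (smallest adjusted p = 0.055) and 0 with an estimated correlation. They became 0 as well by exact permutation of library means. Fry, the estimated correlation and the permutation all allow for members moving together. Over single libraries left out the list count ran from 9 to 13 and the Sox9 log2 fold change from 0.068 to 0.407. The authors' 23 genes became 0 with limma on the same values, and the cause was not tested. The cardiomyocyte list turned to -0.023 without control 201 and in the series block, which leaves out that library (range over single libraries left out -0.023 to 0.709), and the oxidative phosphorylation list to -0.008 after the GC and length adjustment. Of 526 values of 24 named genes across settings, 519 kept direction and side of the threshold, 7 newly passed it and 0 reversed. Complement and antigen presentation, macrophage, smooth muscle, endothelial and ribosomal calls were lost only with the directional form of fry and the estimated correlation, apart from the permutation test. The 1188 genes at unadjusted p under 0.05 became 2131 without labelled knockout 305, 735 without control 404, 651 without labelled knockout 402 and 2063 without both control 201 and labelled knockout 305. The series starting with 4 has 3 libraries per group. No paired analysis was possible because the groups share no column number and no label says which leaflets belong together. DESeq2 size factors and its Wald test, voom and voom with quality weights were planned and not run, since the values are not counts. The planned surrogate variable from sva was not run, and the residual component took its place.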

Other observations

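The X-linked list, the melanocyte values and the principal components were examined after the results were seen, and the test around the Cre driver was added after the first results, before its own value was seen. Melanocyte genes marked single leaflets and not a genotype. Dct, an enzyme of melanin synthesis, read 4.16 in labelled knockout library 401 and 276.1 in control library 403, but 2386 to 4932 in the other libraries. X-linked genes known to escape inactivation averaged -0.28 in the labelled knockouts (exact permutation p = 0.325), with Kdm6a at 123.2 in labelled knockout library 402 and 246.6 in control library 304, against 331.6 to 492.9 elsewhere. The labels give no sex, and Xist and Y-linked genes were not analysed here.

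The first principal component held 31.6% of the variance and did not follow the genotype. Its sign did follow the series given by the first digit of the column number. Control library 201 scored 63.1, labelled knockout library 305 31.1 and control library 304 12.5. Libraries numbered 401 to 407 all scored negative, from -3 in control library 404 to -30.8 and -37.2 in labelled knockout libraries 402 and 407. The main fit had no term for the series, and no label says what the number stands for. Across genes, which are not independent replicates, the loadings of the first component correlated with transcript length (Spearman rho 0.37) and GC content (rho -0.28).

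The position of the Cre allele was not checked. If it lies at Wt1 on chromosome 2, strain variants carried along with the allele might produce differences near that gene. Of 54 tested genes within 10000000 bases of Wt1, 1 (1.9%) had an unadjusted p under 0.05, against 8.8% elsewhere (Fisher's exact p = 0.0869, odds ratio 0.20, 95% interval 0 to 1.15). No excess was seen, and 54 genes are too few to exclude a small one. For a Cre allele inserted elsewhere the test says nothing.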
